A study of Rattus norvegicus with 8 samples.

How the data were processed

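Poly-A selected RNA from the sinus node, the pacemaker tissue of the right atrium, was sequenced in 8 libraries from male wild-type rats of the SD strain, aged 7 to 8 weeks. Per the labels' protocols, the rats behind 4 libraries received alectinib, an inhibitor of the ALK receptor tyrosine kinase, by gavage at 10 mg per kg per day for 7 days, and those behind the other 4 received the solvent. Each library was taken as a separate sample because the labels give it its own title. The labels do not say in so many words that each came from a different animal, so p-values measure the spread between these 8 libraries.

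The authors deposited a table of FPKM values (fragments per kilobase of gene, scaled to the size of the library) for each library, per the file headers. HISAT2 2.0.5, featureCounts 1.5.0-p3 and the genome build mRatBN7.2 are named in the submitters' processing notes. The annotation release, the strand setting and any filter are not given in the sources used here. Each table lists the same 30981 features, of which 30560 carry an Ensembl gene ID and 421 an ID that is not from Ensembl. The files pair no ID with a gene name. The reference gene table used here lists 47357 genes of another assembly, 0 of them with an Ensembl ID, so 0 feature IDs received a symbol. Results by gene name, including Cacna1d and the gene lists fixed before the data were examined, are therefore not analysed here. Positions of features are not given for the same reason.

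Fragment counts and feature lengths were worked out from the FPKM steps. FPKM is a whole number of fragments divided by a whole number of bases and by a library's denominator, so ratios between libraries at low features gave the ratio of denominators, and the remaining steps gave fragments and lengths. Of the 19230 features above 0 in at least 3 libraries, 100.0% came out as whole fragments and whole lengths within 0.03. On 6000 features simulated from these libraries, 5936 were recovered, and 99.5% of those had all 8 fragment counts right. Another 2631 features were above 0 in 1 or 2 libraries and 9120 were at 0 in every library. The recovered totals ranged from 15548382 to 17154306 fragments per library. The authors' denominators lay between 1.7% below and 5.0% above those totals, so the deposited values carried a scaling between libraries besides the total of the listed fragments; what that scaling was is not given in the sources used here. The median number of recovered fragments per library was 26 in the 1420 tested features with a mean FPKM of 0.5 to under 1, 116 in the 4568 at 1 to under 5 and 511 in the 5378 at 5 to under 20, so counting error matters in the first 2 classes.

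The groups were compared with limma 3.58.1 in R 4.3.3 on log2(FPKM + 0.5), with a variance trend over intensity, in the 14247 features with a mean FPKM of at least 0.5 over all 8 libraries. P-values were two-sided and adjusted by the Benjamini-Hochberg method with a threshold of 0.05. Fold changes are on the log2(FPKM + 0.5) scale, which understates the change of low features. The test, the filter, the alternatives (except those said to be chosen later) and the rule for named genes were fixed before the data were examined. That rule asked for genes with a symbol, and said that genes without one would be counted and not named. With 0 symbols, Ensembl IDs were printed in place of genes, a departure from the rule that was not fixed beforehand. Only the 2 IDs with the smallest unadjusted p in each direction whose groups did not overlap are printed.

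The fit was tested on simulated data: fragments were drawn for 14235 of these features, with 50 features changed at each of 4 fold sizes. At 4 libraries against 4, the adjusted threshold called 52% of the 1.5-fold changes, 80% of the 2-fold, 96% of the 4-fold and 100% of the 8-fold changes. Besides these, 9 unchanged features were called. Fragments were drawn independently for each feature, with a spread derived from the one that the fit had estimated. The fit estimated it after a constant was added to FPKM, which shrinks differences between libraries in low features. Low features may therefore have been drawn with too little spread. The draws held no departures of whole libraries such as those of alectinib replicates 2 and 4 below. The Benjamini-Hochberg cutoff also loosens as more features change, so the percentages apply only to the number of features changed in the simulation. With fewer changed features, the same folds would be called less often. The percentages may therefore be higher than the fit would reach on the real libraries.

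A family of 9 measures of whole libraries was compared with exact two-sided permutation tests over the 70 arrangements of 4 against 4, whose smallest possible p is 0.0286. The same fit was repeated on all 35 splits of the 8 libraries into 4 and 4. Alternatives covered the pseudocount (0.1 and 1), the filter (none, and a mean FPKM of at least 1), the scaling between libraries, the variance model, weights per library, the replicate number as a block, other thresholds, and each library left out in turn. The labels name no batch. Samples with the same replicate number were checked for shared deviations from their group means. The correlations were 0.061, -0.044, 0.021 and 0.128 for numbers 1 to 4, which did not meet the condition of over 0.1 in every pair, so the numbers were not used to pair samples. Whether library size accounts for the libraries that depart most was first tested against vehicle replicate 2 alone, then by thinning all libraries to the lowest total. Both were dropped after their results were seen: the first left out other libraries of like size, and thinning adds counting noise to the larger libraries and its value changed with the random draw. The rank correlation over all 8 libraries took their place. Python 3.11.15 with numpy 2.4.6 and pandas 2.3.3 was used for the remaining steps.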

Results

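The sinus node transcriptome was measured by RNA-seq in 4 libraries from rats given alectinib, a kinase inhibitor used against ALK-positive tumours, and in 4 from rats given its solvent. The series is about slow heart rate of sinus node origin under alectinib, and its design sets the RNA profile of the treated group against that of the vehicle group. Recovered totals were 16195636, 17079469, 16257190 and 15548382 fragments in vehicle replicates 1 to 4, and 16288424, 17029281, 16467951 and 17154306 in alectinib replicates 1 to 4. Between 18400 and 18653 of the 30981 listed features had a value above 0 in a library, and between 12767 and 12875 reached an FPKM of 1.

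The comparison of alectinib with vehicle asked which transcripts of the sinus node changed with treatment. None of the 14247 features tested passed the adjusted threshold in limma, and the smallest adjusted p was 0.732. The count was 1 without vehicle replicate 2 (adjusted p = 0.0373), 1 without vehicle replicate 3 (0.0217), 0 without any other single library, and 2 with alectinib replicates 2 and 4 left out together (0.00971), a setting chosen after seeing the data. An unadjusted p under 0.05 was reached by 842 features, with 423 higher and 419 lower under alectinib. A share of 5% of the features tested is 712, but other splits of the 8 libraries into 4 and 4 varied widely around it. They gave 385 to 1250 features, with a median of 615. For alectinib against vehicle with 1 library left out, the count ranged from 540 to 1120, with 540 without vehicle replicate 2. By limma's voom method on recovered fragments, 0 features passed the adjusted threshold and 845 had an unadjusted p under 0.05. The near-even division of higher and lower features held under some scalings between libraries and not under others. It was 422 higher against 417 lower with median-of-ratios scaling, and 411 against 449 with quantile normalization. After rescaling to TPM it was 247 against 664, and after scaling by the recovered totals 300 against 557. The title of the series names Cacna1d, a pore-forming subunit of L-type calcium channels, but its row was not matched in these files, so its value is not analysed here.

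The 2 Ensembl IDs with the smallest unadjusted p in each direction, among those whose groups did not overlap, differed by less than 2-fold. Their ratios are of FPKM + 0.5, averaged on the log2 scale. They are therefore less extreme than ratios of the printed FPKM means, most clearly for ENSRNOG00000026527. ENSRNOG00000021637, with a summed length of 3630 bases, stood at 18.7 ± 1.1 FPKM under vehicle and 25.7 ± 1.36 under alectinib (SD, n = 4 each), a ratio of 1.37 with a 95% interval of 1.23 to 1.52. ENSRNOG00000058561, of 10358 bases, stood at 38.6 ± 0.87 FPKM under vehicle and 49.9 ± 2.23 under alectinib, a ratio of 1.29 with an interval of 1.18 to 1.41. In the other direction, ENSRNOG00000026527, of 2006 bases, stood at 2.83 ± 0.34 FPKM under vehicle and 1.64 ± 0.03 under alectinib, a ratio of 0.644 with an interval of 0.546 to 0.759. ENSRNOG00000007567, of 1622 bases, stood at 12.2 ± 1.59 FPKM under vehicle and 8.43 ± 0.47 under alectinib, a ratio of 0.707 with an interval of 0.607 to 0.823. The limma adjusted p was 0.732 for each of the 4, and their unadjusted p ranked 1, 2, 3 and 5 among all features tested, so they were picked as extremes and their intervals are not adjusted for that choice. Between 52 and 109 fragments per library lay behind ENSRNOG00000026527, and at least 205 behind each of the others.

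**Figure D1:**
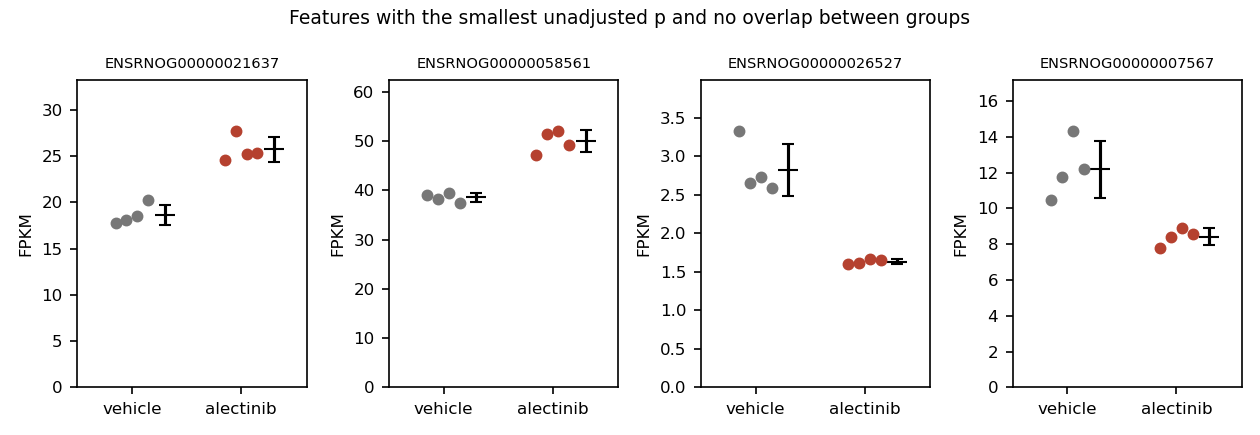
FPKM (linear axes from 0) of the 4 printed features in each library, with vehicle libraries in grey, alectinib libraries in red and the group mean with its SD (n = 4) in black. The groups did not overlap in any of the 4, and the ratios of alectinib to vehicle were 1.37, 1.29, 0.644 and 0.707.

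In 528 features, 3.71% of those tested, every alectinib library lay on the same side of every vehicle library. Chance gives 2.86% on average if the libraries are interchangeable, but single splits varied widely around that share. Of the 35 splits of the libraries into 4 and 4, the real one included, 5 gave at least 528. The other splits gave 228 to 708. Of the 528 features, 268 were higher and 260 lower under alectinib. An unadjusted p under 0.05 together with a change of at least 2-fold was found in 38 features, 20 higher and 18 lower. None of the 446 features with a mean FPKM of 100 or more was among them.

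The intervals limited the size of the difference between the 2 groups of libraries for most features. The 95% interval of the ratio lay wholly within a 2-fold change in either direction for 13282 features, 93.2% of those tested, and within a 1.5-fold change for 77.9%. The median half-width of the interval corresponded to 1.21-fold. It was narrower for abundant features, at 1.15-fold for a mean FPKM of 20 to under 100, and wider at 1.41-fold for a mean FPKM of 0.5 to under 1. For 965 features, 337 of them with a mean FPKM of 0.5 to under 1 and 401 with 1 to under 5, a 2-fold change was not excluded. These counts depend on the pseudocount of 0.5, which shrinks the ratios of low features: the share within 2-fold was 88.4% with a pseudocount of 0.1 and 95.7% with a pseudocount of 1. By voom it was 87.2%. Intervals cover the spread between libraries and are not adjusted for the number of features.

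Features whose ID is not an Ensembl gene ID were considered apart from those with one. Of the 362 tested, 34 (9.39%) had an unadjusted p under 0.05, with 16 higher and 18 lower, and 0 passed the adjusted threshold in limma. Among the 13885 tested features with an Ensembl ID, 808 (5.82%) had an unadjusted p under 0.05 and 0 passed. The difference between the 2 shares was not tested. The median log2 ratio was -0.03 in the first class and 0.00 in the second, and the middle 50% of ratios ran from -0.22 to 0.18 and from -0.09 to 0.10. The features without an Ensembl ID were lower in depth, with a median of 37 recovered fragments per library. Together they took 0.344 ± 0.011% of fragments under vehicle and 0.381 ± 0.045% under alectinib (SD, n = 4 each, exact two-sided permutation p = 0.143).

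The first 2 principal components did not separate the groups. The first principal component held 22.5% of the variance and set alectinib replicate 4 apart with a score of 39.3, against -15.1 to 5.8 in the other 7 libraries. The second, with 16.6%, set alectinib replicate 2 apart with a score of 33.9, against -12.9 to 1.2 in the others. The third, with 14.6%, ran from -14.7 to -0.9 in the alectinib libraries and from -6.4 to 28.9 in the vehicle libraries, with vehicle replicate 1 alone among the alectinib scores and vehicle replicate 4 highest. Pearson's r of log2 values across features was 0.964 to 0.981 for the 12 pairs of libraries within a group and 0.967 to 0.980 for the 16 pairs across groups, with features as units that are not independent replicates. Fragment counts of every pair differed by more than counting noise, with a chi-square per degree of freedom of at least 10.03, so no library was taken as a copy of another.

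**Figure D2:**
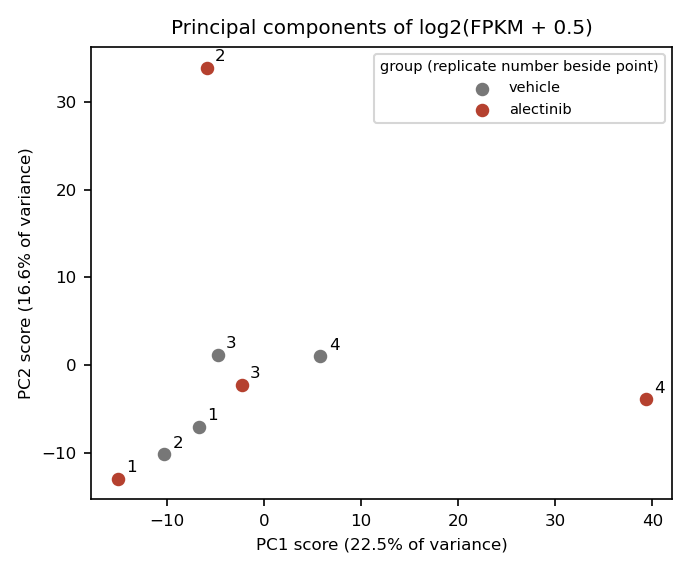
Scores of the 8 libraries on the first (22.5% of variance) and second (16.6%) principal components of log2(FPKM + 0.5), vehicle in grey and alectinib in red, with the replicate number beside each point. Alectinib replicates 4 and 2 lie apart. Alectinib replicate 3 lies among the vehicle libraries, and alectinib replicate 1 has the lowest score of the 8 libraries on both components (-15.1 and -12.9).

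For the 9 measures of whole libraries, exact two-sided permutation p between the groups was 0.143 or higher, where 0.0286 is the smallest possible. With that floor, adjustment over 9 measures leaves a single separated measure above the threshold, so these values are given unadjusted. Recovered totals gave an exact p of 0.2. The 10 most abundant features took 17.2 ± 0.751% and 17.6 ± 0.653% of fragments (SD, n = 4 each, exact p = 0.543). Features above 0 numbered 18495 ± 74.9 under vehicle and 18562 ± 71.4 under alectinib (SD, n = 4 each, exact p = 0.286). Authors' denominators stood at 1.01 ± 0.0268 and 0.997 ± 0.0115 of the recovered totals (SD, n = 4 each, exact p = 0.4).

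**Figure D3:**
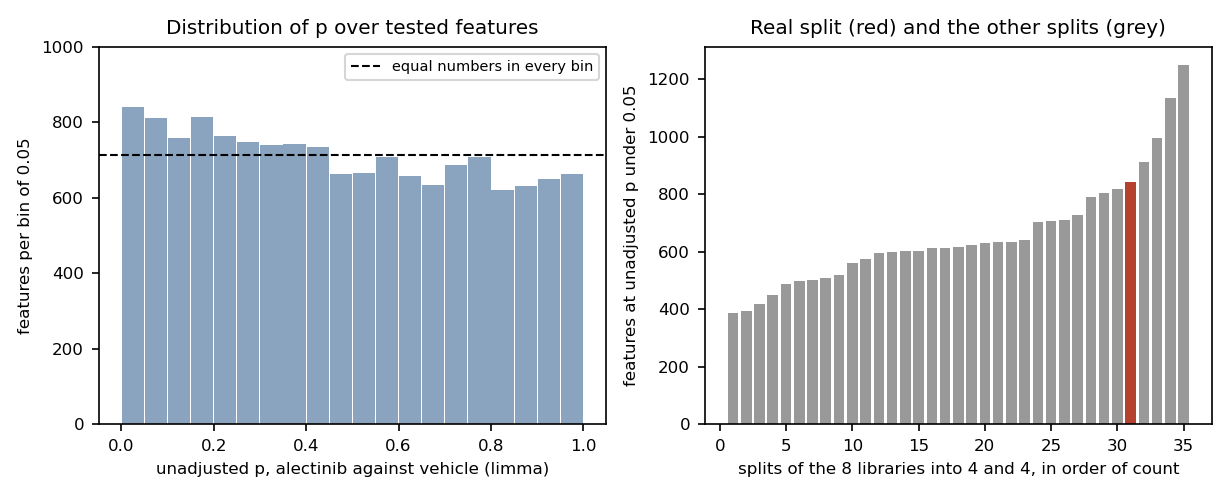
Left, number of features per bin of 0.05 in unadjusted limma p for alectinib against vehicle, with a dashed line at equal numbers per bin. Right, number of features at an unadjusted p under 0.05 for each of the 35 splits of the 8 libraries into 4 and 4, in order; the real split (red) gave 842, and the highest other split gave 1250.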

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

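Values per library were tested for a library far from the other 3 of its group, over 36 combinations of measure and group. They covered the measures of whole libraries, the principal component scores and the FPKM of the printed features. Counts of features over 2-fold higher or lower than the median of the other 7 libraries were also covered. Other values given below, such as the fragment share of the features raised in alectinib replicate 4 and the rise per doubling of length, were not tested. None of the 36 met Dixon's 95% criterion of 0.829, where chance alone would flag about 1.8 of the 36. The nearest was the vehicle replicate 1 value of ENSRNOG00000026527, whose gap to the next library was 0.815 of the group's range. Next came the count of features over 2-fold higher in alectinib replicate 4, at 0.813. With 4 libraries in a group the criterion is strict, so the lack of a flag does not show that no library stood apart.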

How the results depend on the processing

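The alternatives of voom on recovered fragments, scaling by recovered totals, removal of a length trend and leaving out alectinib replicates 2 and 4 together were chosen after seeing the data. The count of features past the adjusted threshold, 0, was also 0 under 22 of 25 alternatives. Among the 22, the alternative that added a 2-fold condition to the main fit could only give 0. With 1 library left out it ranged from 0 to 1: it was 1 without vehicle replicate 2 and 1 without vehicle replicate 3, and 2 with alectinib replicates 2 and 4 left out together; the cause was not tested, and none of these calls was among the 4 printed features. The count at an unadjusted p under 0.05 ranged from 540 to 1120 with 1 library left out, with 540 without vehicle replicate 2, and from 796 to 1006 under the others that tested about the same features. It was 770 of 12827 features with a mean FPKM of at least 1 and 1155 of 21861 with no filter, which mostly follows the number tested. The share of features whose interval lay within a 2-fold change ranged from 87.2% to 95.7%. The 4 printed features missed the adjusted threshold under all 23 alternatives run on them, with limma adjusted p from 0.296 to 0.999. They also kept their direction, which says little. They were picked for groups that did not overlap, so leaving out libraries or changing the pseudocount could not reverse it. With the replicate number as a replicate block, 0 features passed and 796 had an unadjusted p under 0.05; 2 of the 4 numbers matched best across groups, and no call changed. The alternatives that need gene names (Cacna1d, gene lists, mitochondrially encoded genes left out, an atrial covariate) were not run. Precision at low features was limited by depth: 3 fragments in a feature of 1 kb correspond to an FPKM of 0.174 to 0.187.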

Other observations

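The tests on other splits of the samples and on the departures of single libraries concern patterns seen in the data. The split counts, the library size tests and the length test of alectinib replicate 2 were chosen after the result was seen, and the length and co-variation tests of alectinib replicate 4 before. The library size tests replace others that were run first and dropped, as described in the processing section.

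The number of features that separated alectinib from vehicle was within what other divisions of the same libraries gave, so chance cannot be excluded. Of the 35 splits of the 8 libraries into 4 and 4, the real one included, 5 gave at least the 842 features at an unadjusted p under 0.05 of the real split, and the highest other split gave 1250. That split set vehicle replicates 1, 2 and 3 with alectinib replicate 1 against the other libraries. At the adjusted threshold the real split gave 0 features and the highest other split 1; with a real count of 0 all 35 splits give as many, so that count says nothing about chance. For features with an unadjusted p under 0.05 and a change of at least 2-fold, the real split gave 38, and 30 of 35 splits gave as many, with a median of 43 and a highest of 63 among the others. A list drawn up by unadjusted p and fold alone would thus be about as long for arbitrary groupings of these libraries. The sum of squared log2 differences over all features was 627.2 for the real split, and 19 of 35 splits gave as much.

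Alectinib replicate 4 held the largest number of raised features of the 8 libraries. In it, 227 features with a mean FPKM of at least 1 were over 2-fold above the median of the other 7 libraries, against 54 to 101 in each of the others. Against the mean of the other 7, in features with a mean FPKM of at least 1 in those 7, 207 were over 2-fold higher, 21 of them over 4-fold and 4 over 8-fold. These 207 took 1.06% of its fragments and 0.36% to 0.49% in the other libraries.

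The root mean square log2 departure of alectinib replicate 4 from the mean of the other 7 was 0.393, against 0.285 to 0.343 in the rest. Of the 3 libraries with the most fragments, 2 departed most (alectinib replicates 4 and 2) and vehicle replicate 2 stood at 0.297; over all 8 libraries the rank correlation of the total with the departure was 0.357 (exact one-sided p = 0.195), so library size stays open, with too few libraries to decide it. Removing each library's length trend took away -0.2% of the excess of alectinib replicate 4 over the median library, so none of it, which speaks against a length bias. A larger share of some tissue component in that dissection stays open: its 207 features correlated with each other over the other 7 libraries by a mean of 0.009, above 97.39% of 10000 matched random sets, as the hypothesis predicted, but the correlation was so small that it gives the hypothesis little weight. A response to alectinib in 1 of the 4 treated libraries was not tested and stays open too.

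Alectinib replicate 2 departed second most, at 0.343, and its departure rose with feature length, with a correlation of 0.236 across features against -0.087 to 0.02 in the other 7 libraries. Its log2 level rose by 0.067 per doubling of length. Removing the length trend took away 24.2% of its excess departure, so a length bias may account for a part of what sets this library apart and not for the whole. Library size stays open here too, by the same rank correlation of 0.357. After the length trend was removed from all libraries, 0 features passed the adjusted threshold and 893 had an unadjusted p under 0.05.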
